A study of Homo sapiens with 2 samples.

How the data were processed

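ATAC-Me libraries of H9 human embryonic stem cells were analysed, 2 replicates of 1 group. For each replicate the authors deposited a table of CpGs with a methylation fraction (0 to 1, methylated reads over reads covering the CpG) and a count of covering reads, without a header; CpGs without reads are listed with a fraction of 0 and were left out. The authors also deposited 1 peak list for the group, with a score capped at 1000, a peak signal (the caller's own value, used here only to rank and describe peaks), the −log10 of the q-value and the summit position. Per the submitters' processing notes, Trim Galore and Genrich were used with the build hg38, also named GRCh38; the mapper, the methylation caller, tool versions and the way replicates were combined for peak calling are not given in the sources used here. Whether duplicate reads were removed is also not given, and reads without molecular identifiers are not independent molecules, so intervals cover counting error only. The tables hold reads on converted DNA; a cytosine that failed to convert reads as methylated and raises low values most. Reads outside peaks are spread over many more CpGs, so values there rest on few reads per CpG.

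Methylated reads were computed as the fraction times the reads, rounded to whole numbers; over 99.9% of products were whole within 0.001. The methylation of a region is its methylated reads over its reads, in percent, computed in each replicate and then averaged, with the SD over 2 replicates. A region's reads are summed over its CpGs, so a read covering several CpGs is counted at each of them. Fragments are thus fewer than the reads given. Wilson intervals are too narrow and p-values of Fisher's exact test per peak too small. Autosomal CpG reads in peaks totalled 14065562 and 18562168, with a median of 104 and 125 reads per tested peak. Peaks needed at least 10 CpG reads in each replicate, genes at least 20 within 500 bp, and named methylated peaks at least 50. Of the autosomal peaks, 2309 held no CpG.

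Promoters could not be used as planned, because the gene table (assembly GRCh38.p14) gives the ends of genes but not their strand. A stand-in was chosen after the data were examined: the end of a protein-coding gene with at least 2 times as many CpGs within 500 bp as the other end. It was found for 15315 of 19974 genes on chromosomes 1 to 22 and X. Of 52 genes of well-known direction, 37 had such an end and it was the right one for 34; AFP, APOA1 and TTR, where it was wrong, were left out of the gene lists. A peak lay at 72.0% of the assigned ends and at 5.45% of the other ends. A peak with its summit within 1000 bp of an assigned end is a gene end peak, a peak more than 1000 bp from both ends of every protein-coding gene is distal, and the remaining 3.70% entered neither class. Genes without such an end were not analysed here, except under an alternative. TDGF1 and C1orf43 are listed under their current symbols, CRIPTO and LTAP1.

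Each gene list, fixed before the data were examined except for the 3 genes left out above, was compared with 10000 random lists of the same size and CpG density deciles; the two-sided permutation p of its median was Benjamini-Hochberg adjusted over the 13 lists with at least 5 measured genes. Replicates were compared per peak with Fisher's exact test, two-sided, adjusted over peaks at 0.05. All other comparisons give differences beside the SD between replicates. Genes and peaks were named by a rule fixed in advance: by class, methylated peaks and intermediate peaks of highest signal, strongest unmethylated distal peaks, largest replicate differences, and in each list the lowest and highest genes or, for lists of up to 35, any member. Some peaks that the rule takes are not reported here. Peaks at an assigned end were found with the coordinates of the same build; coordinates are counted from 1.

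On simulated data with the reads of the 40703 peaks, the per-peak test called 37.0% of 100 peaks raised by 10 points and 76.0% of 100 raised by 30 points, and 2.59% of its calls were unchanged peaks. The simulated reads were independent, without a shift between libraries and without the overdispersion of 2.90 found in the data. That factor was computed with the shift between libraries left in. These shares therefore need not hold for the real libraries. Of 200 random gene lists, 6.50% passed 0.05 before adjustment, and all of 200 lists with 12 of 20 genes raised by 20 points did. Such a raise lifts the median of any list to at least 20%, so that last share was all but fixed in advance. It says nothing on the smaller differences of most lists tested here. The alternatives covered read minimums, the significance of peaks, class limits, weighting, the distance to gene ends, the background of outside CpGs, matching on coverage, and each replicate left out. Comparison of distal peaks with transcription factor motifs needs a genome sequence and was not analysed here, and chromosome X entered no peak comparison. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9.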

Results

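Accessible chromatin and its DNA methylation were measured together in H9 cells, a line of human embryonic stem cells kept pluripotent in culture. The assay, ATAC-Me, inserts sequencing adapters into open chromatin with a transposase and then converts unmethylated cytosines, so that each fragment reports accessibility by its position and methylation by its sequence. There was 1 group, undifferentiated H9 cells, with 2 replicates, and no treated group. The replicates held 29270697 and 52758656 reads over the CpGs of chromosomes 1 to 22 and X, and covered 31.2% and 58.3% of the 29175448 CpGs listed there. The peak list held 46980 regions, of which 46884 lay on the autosomes, with a median width of 295 bp and a total length of 17.7 Mb. No peak was listed on chromosome X, so the comparisons below use the autosomes. Nothing in the labels says whether the replicates came from separate cultures, so the spread between them may be technical.

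The design asks first how methylated open chromatin is in these cells. DNA inside accessible regions was almost free of methylation, while the rest of the genome sampled by the assay was mostly methylated. Inside peaks 2.82% and 3.51% of CpG reads were methylated in replicates 1 and 2, a mean of 3.17% ± 0.489 (SD, n = 2). Outside peaks the values were 61.1% and 70.03%, a mean of 65.6% ± 6.34 (SD, n = 2). The difference of −62.4 ± 5.85 percentage points (SD, n = 2) was larger than the spread between replicates. Peaks took 49.4% and 36.1% of the autosomal CpG reads, with a mean of 15.2 and 20.05 reads per covered CpG inside against 1.83 and 2.12 outside. An exact sign-flip permutation test of 2 paired differences cannot give a two-sided p below 0.5, so no p is given. The size of the difference depends on which outside CpGs are counted: it was −28.4 points over CpGs with at least 5 reads, each weighted equally, and −11.6 points over CpGs with at least 10 reads.

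Most peaks were unmethylated, fewer were partly methylated and very few were fully methylated. Among the 40703 autosomal peaks with at least 10 CpG reads in each replicate, 74.3% ± 0.806 had under 20% methylation, 24.7% ± 0.823 had 20% to 80% and 1.04% ± 0.0174 had over 80% (SD, n = 2). Peaks at the ends of protein-coding genes chosen as the stand-in for promoters, called gene end peaks here, were nearly all unmethylated: 98.9% were under 20% and 0.0428% were over 80%. Distal peaks, more than 1000 bp from both ends of every protein-coding gene, were under 20% in 65.1%, between the limits in 33.5% and over 80% in 1.41%. The share over 80% fell to 0.411% with at least 30 reads per peak and to 0.308% among peaks above the median significance of the list. Reads of closed chromatin that fall within a peak, called background here, were not taken off. How far they raise the share of partly methylated peaks was not tested.

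Gene end peaks read as less methylated than distal peaks at every CpG density, before any correction for background. The median gene end peak had 0.860% ± 0.649 methylation and the median distal peak 9.94% ± 0.851 (SD, n = 2), a difference of −9.07 ± 0.203 points that exceeded the spread between replicates. Within deciles of CpG density the gene end median was lower in each of the 10 deciles. The gap was widest in decile 3, at −13.0 ± 2.09 points, and narrowest in the densest decile, at −0.151 ± 0.0455 points (SD, n = 2). The lowest 2 deciles held only 24 and 30 gene end peaks. The gap was −5.53 points with at least 30 reads per peak and −4.81 points among peaks above the median significance. Background may account for part or all of the gap. Background reads were estimated from CpG coverage 2000 to 10000 bp away. The 14561 distal peaks used had at least 50 reads and left out the fully methylated ones. Background made up a median of 4.75% and 9.91% of their reads in the replicates. Outside CpGs at that distance were 70.2% and 77.5% methylated. The background share was not computed for gene end peaks. It was not taken off, so its part in the gap was not tested.

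**Figure D1:**
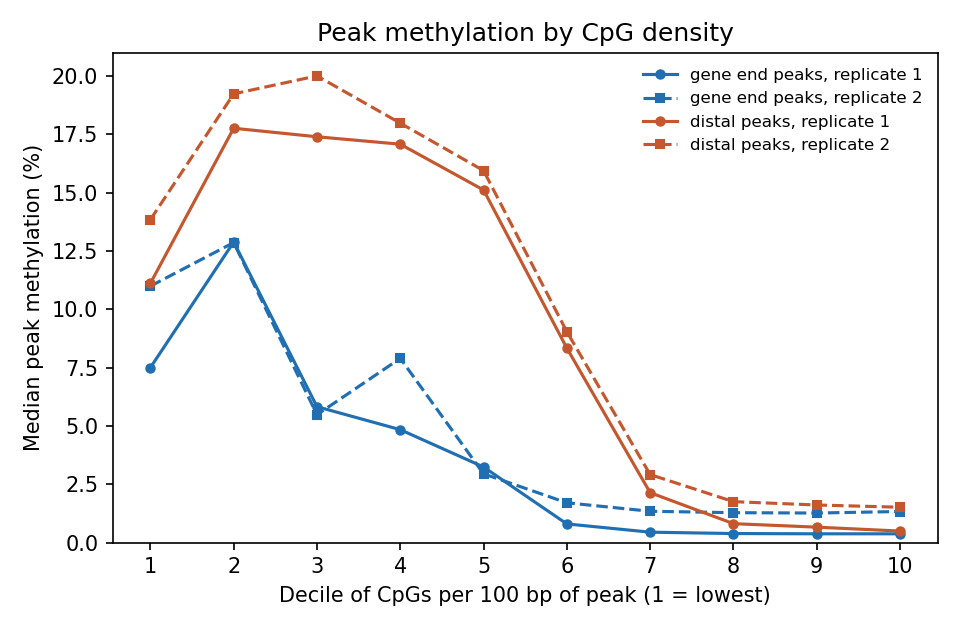
Median peak methylation (%, vertical axis) by decile of CpGs per 100 bp of peak (horizontal axis) for gene end and distal peaks, with a line for each replicate. Distal medians are 12.5% in decile 1, 18.7% in decile 3 and 1.005% in decile 10, and gene end medians lie below them in each decile.

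Stronger peaks were less methylated, and so were CpG-rich ones. Across peaks, which are not independent replicates, Spearman's rho of methylation was −0.535 ± 0.0248 with CpG density and −0.397 ± 0.0181 with the authors' peak signal (SD, n = 2). Within density deciles the rho with signal was −0.258 ± 0.0124, and among gene end peaks alone it was −0.103 ± 0.0377 with signal and −0.112 ± 0.0377 with density (SD, n = 2). The fall with density was not seen at low density: the median of all peaks was 12.5% in the CpG-poorest decile, 18.5% in decile 3 and 14.7% in decile 5. Distal peaks in the lowest signal decile had a median of 22.1% ± 1.53 and those in the highest 1.53% ± 0.718 (SD, n = 2). These values were not corrected for background either, so its part in the relation with signal was not tested.

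Methylation was lowest at the summit of a peak and rose with distance from it. Around gene end peaks it was 0.892% ± 0.618 within 50 bp of the summit and 9.57% at 950 to 1000 bp, a rise of 8.67 ± 2.51 points (SD, n = 2). Around distal peaks it was 7.33% within 50 bp and 26.3% ± 7.17 at 950 to 1000 bp (21.3% and 31.4% in the replicates), a rise of 19.01 ± 6.95 points (SD, n = 2). Both rises exceeded the spread between replicates. The median width was 507 bp in gene end and 279 bp in distal peaks, so 950 to 1000 bp mostly lies outside them. Reads fell with distance, in replicate 1 from 2565866 to 126763 around gene end and from 1760830 to 112175 around distal peaks. Background can thus weigh more away from the summit. It was not taken off, so its part in the rises was not tested.

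**Figure D2:**
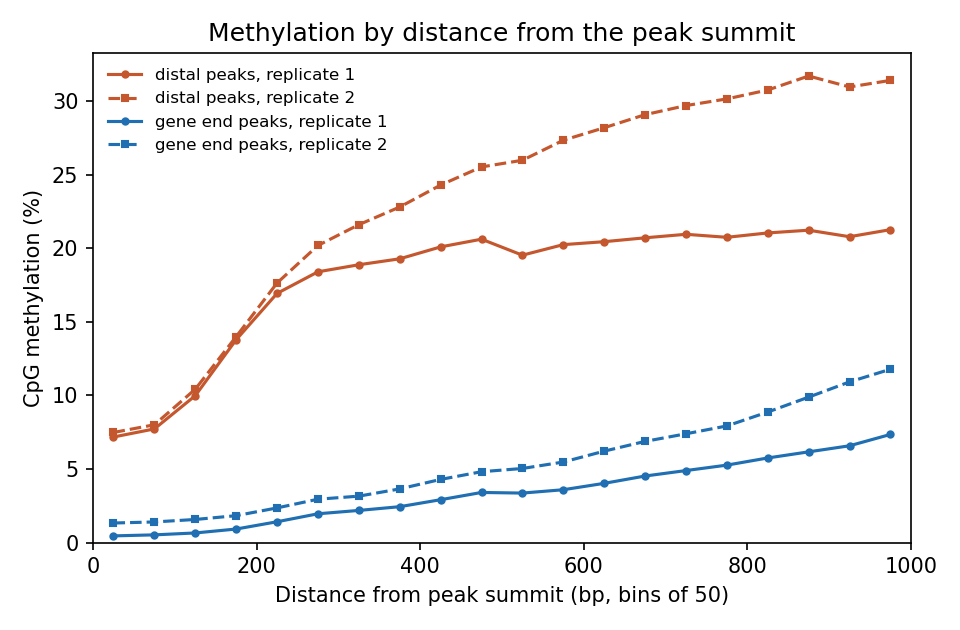
CpG methylation (%, vertical axis) against distance from the peak summit (bp, horizontal axis, bins of 50 bp) for gene end and distal peaks, with a line for each replicate. Within 50 bp of the summit the mean is 0.892% in gene end peaks and 7.33% in distal peaks.

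Germline genes had the highest methylation of the 13 tested lists, and few of them had a peak. The 21 measured members of the germline and meiosis list had a median of 89.2%, against 1.496% in random lists matched on CpG density (permutation p = 0.0002, the smallest 10000 lists can give; adjusted p = 0.0013). Over 80% methylation in both replicates was seen at 13 of them, including STK31 (97.0% ± 4.31, SD, n = 2), DMRTB1 (95.9% ± 3.95), BRDT, a testis bromodomain protein (94.1% ± 0.691), and DAZL, an RNA-binding protein of germ cells (91.5% ± 0.256). Reads were few at these ends, 24 and 92 at DAZL; with at least 50 reads in each replicate 9 genes were left, with a median of 38.7% (adjusted p = 0.00087 by permutation). MAEL (1.03%) and TDRD1 (2.90%), both of the piRNA pathway, were unmethylated, and LDHC, a testis lactate dehydrogenase, was at 17.6%. Only 4 of the 21 had a peak within 1000 bp, against 17 in matched lists (adjusted p = 0.0013 by permutation).

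The measured core and primed pluripotency genes were mostly open and unmethylated, like most measured gene ends. Of the 32 listed, 23 were measured, and POU5F1 and NANOG were not among them. Under 20% in both replicates were 20 of the 23, against 93.4% of all measured autosomal gene ends. A peak lay near 17 of the 23, against 19 in matched lists (adjusted p = 0.59 by permutation). The median was 1.03% (adjusted p = 0.37 by permutation). SOX2 was at 1.19% ± 0.857, DNMT3B, a de novo methyltransferase, at 1.03% ± 0.494, LIN28A at 1.91% ± 0.673 and SALL4 at 1.43% ± 1.36 (SD, n = 2). The exceptions were LIN28B (97.4% ± 3.61), ZSCAN10 (94.4%) and DPPA2 (65.4% ± 8.72). The assigned end of DPPA2 is the right one by its known direction. LIN28B and ZSCAN10 were not in that check, so their assigned ends may not be promoters. In the naive pluripotency list, 7 of 19 genes were measured. A peak lay near 3 of the 7, against 6 in matched lists (adjusted p = 0.090 by permutation). Over 80% in both replicates were 3 of the 7: OOEP (93.5%), DPPA5 (89.2%) and HORMAD1 (89.2%), the last of which is also in the germline list. KLF4 (0.874%), TFAP2C (1.07%), TFCP2L1 (1.74%) and FGF4 (2.23%) were unmethylated. The list's median of 2.23% did not pass (adjusted p = 0.19 by permutation), while it passed at 86.3% with CpGs within 1000 bp (adjusted p = 0.0007 by permutation), at 85.8% with at least 10 reads (0.00087) and at 19.7% with the CpG-richer end of every gene (0.0035).

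The measured genes of later lineages carried little methylation at their gene ends, with few exceptions. Measured were 17 of 22 neural progenitor, 14 of 18 mesoderm, 6 of 14 endoderm and 6 of 14 trophoblast genes. The others had no assigned end, too few reads or a wrong end. The medians need not hold for the whole lists. All 17 measured neural progenitor genes were under 20% in both replicates and 15 had a peak, the same as in matched lists, 15. Their median of 0.750% was below that of matched lists, 1.13% (adjusted p = 0.045 by permutation). Among these genes were NEUROG2 (0.367%), POU3F2 (0.404%), PAX6 (0.843%) and SOX1 (1.06%), all transcription factors of neural development. In the replicates the list's medians were 0.391% and 1.04%, with an SD of 0.462. Peaks with at least 8 CpGs per 100 bp and 500 reads in each replicate had medians of 0.385% and 1.31%. The difference from matched lists is thus one between values near the unmethylated level of these libraries. The call was lost in 4 of 9 alternatives by permutation: with CpGs within 250 bp (adjusted p = 0.18), at least 50 reads (0.064), shared gene ends counted once (0.057) and without replicate 2 (0.25), where the median was 0.391%. Mesoderm genes had a median of 1.17% (adjusted p = 0.82 by permutation), with EOMES at 0.221%, TBXT at 0.982% and MSGN1 as the exception at 85.1%. Endoderm genes had a median of 0.970% (adjusted p = 0.71 by permutation), with 2 of 6 near a peak, against 5 in matched lists (adjusted p = 0.042 by permutation). FOXA2 (1.88%), GATA6 (0.679%) and HHEX (1.61%) were unmethylated and had no peak within 1000 bp. Trophoblast genes had a median of 3.55% (adjusted p = 0.13 by permutation), with TP63 at 88.0% and TFAP2A at 2.09%. The trophoblast median was 5.21% without replicate 2 (adjusted p = 0.051 by permutation), 1.98% without replicate 1 (0.73), 2.13% within 250 bp (0.061) and 8.64% within 1000 bp (0.073).

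HOX genes, the patterning genes of the body axis, were unmethylated but largely without peaks. All 28 measured members were under 20% in both replicates, from HOXA13 (0.599%) to HOXB1 (8.77%), and 7 had a peak within 1000 bp, against 24 in matched lists (adjusted p = 0.0013 by permutation). Their median of 2.90% was above the 1.15% of CpG-matched lists (adjusted p = 0.0035 by permutation), but not past the test against lists matched on coverage as well (adjusted p = 0.90 by permutation). It was 1.72% within 250 bp (adjusted p = 0.0095 by permutation) and 1.94% without replicate 2 (0.0104). HOX genes lie in clusters and are not independent of each other.

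Imprinted genes, in which the copy from a given parent is methylated at control regions, were above matched genes but far from an even mixture of methylated and unmethylated copies. The 22 measured members had a median of 4.32%, against 1.19% in matched lists (adjusted p = 0.0013 by permutation). The median was 1.80% without replicate 2, where the call was lost (adjusted p = 0.051 by permutation), and 5.24% without replicate 1. The highest were GNAS (20.5% ± 0.758), DIRAS3 (20.3% ± 3.03), NAP1L5 (19.1% ± 13.7) and NNAT (11.5% ± 16.2, SD, n = 2), and the lowest ZDBF2 (0.515%) and BLCAP (0.728%). NNAT read 0% in replicate 1 (171 reads summed over 79 CpGs, 95% Wilson upper bound 2.20%) and 22.9% in replicate 2. That bound is too low where CpGs share reads. Assigned ends need not be the control regions of these genes.

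Housekeeping genes were unmethylated, with a median of 0.975% (adjusted p = 0.68 by permutation) and a peak at 19 of 20, against 17 in matched lists. The DNA methylation genes were unmethylated too, at 1.03% (adjusted p = 0.68 by permutation), with TET1 at 3.36%, DNMT3A at 2.33% and DNMT1 at 1.03%. A peak lay near 11 of the 13, the same as in matched lists, 11. Only 8 of the 392 listed olfactory receptor genes were measured, with a median of 17.6% (adjusted p = 0.19 by permutation). With at least 10 reads per gene the list passed at 80.3% (adjusted p = 0.0026 by permutation). Within 1000 bp the median was 46.9% (adjusted p = 0.11 by permutation). The 26 measured clustered protocadherin genes had a median of 13.2% (adjusted p = 0.045 by permutation), a call lost in 7 of 9 alternatives. For 7 of the 26, all gamma protocadherins, the assigned end is the same one (2.30%), probably the far end of the cluster and not a promoter. The median was 29.3% when a gene end shared by several members was counted once (adjusted p = 0.087 by permutation), 3.75% within 250 bp (0.15), 3.12% with at least 50 reads (0.19) and 2.30% with the CpG-richer end of every gene (0.65). Among them PCDHA3 (97.9%), PCDHA7 (96.7%) and PCDHA6 (91.4%) were highest and PCDHAC1 (0.552%) lowest. Fewer than 5 genes were measured in the fibroblast, blood and keratin lists, which were not tested; the fibroblast genes VIM, COL1A2 and COL1A1 read 1.62%, 3.22% and 28.5%, the blood genes HBA1, CD37 and LCK 3.28%, 50.9% and 86.4%, and KRT5 88.3%. Most low medians followed the library left in. Without replicate 2 and without replicate 1 they were 0.356% and 1.42% for housekeeping genes, 0.523% and 1.504% for core and primed pluripotency, 0.553% and 1.78% for mesoderm and 0.746% and 1.68% for endoderm. The medians of naive pluripotency (2.44% and 2.02%) and trophoblast genes (5.21% and 1.98%) went the other way. The p-values of medians were adjusted over the 13 lists, those of peak counts separately over the same lists, and those of each alternative in its own run.

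**Figure D3:**
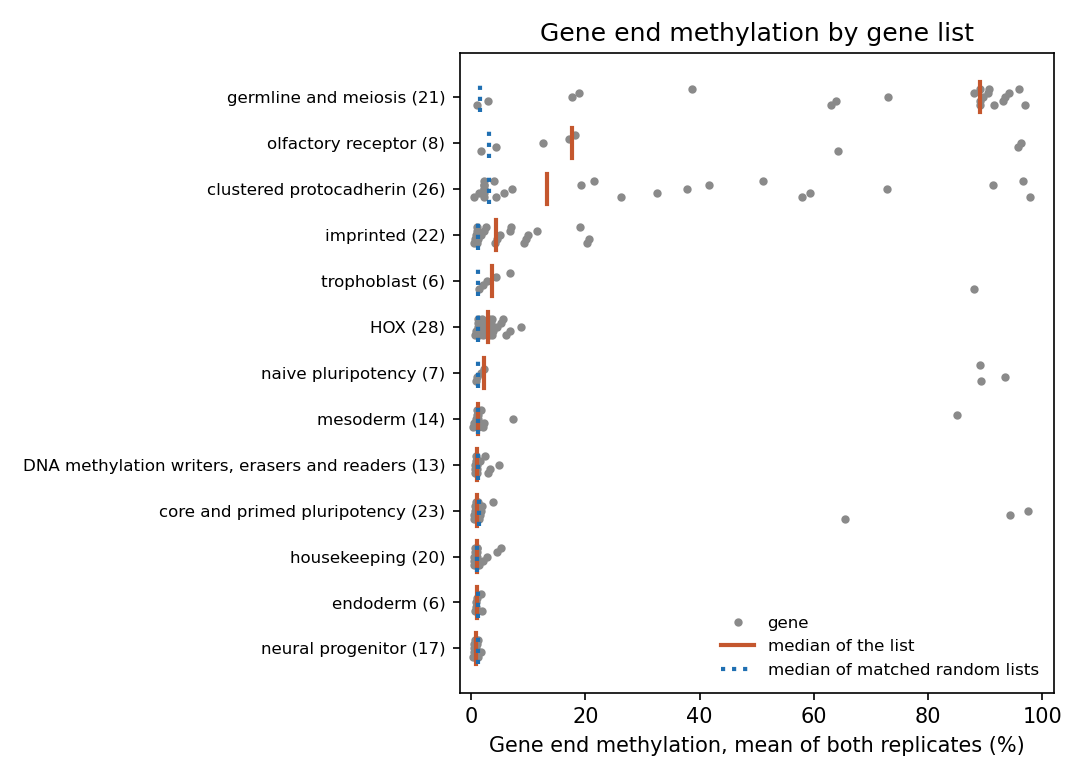
Gene end methylation (%, horizontal axis, mean of both replicates) of each measured gene (points) in the 13 tested lists (vertical axis, with the number measured), the median of each list (solid mark) and the median of CpG-matched random lists (dotted mark). The germline and meiosis median of 89.2% stands far from its matched value of 1.496%.

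A few peaks read as methylated, though background above that estimated from nearby coverage and narrow repeats remain open for the distal ones. Of 26116 peaks with at least 50 CpG reads in each replicate, 31 were over 80% methylated in both, 2 of them at gene ends and 29 distal. The 29 had a median signal of 424, against 722 in other distal peaks with at least 50 reads. The gene end peaks lay at C5orf58 (chromosome 5, 170232860 to 170233041, 84.9% ± 1.64) and PTH2R (chromosome 2, 208359567 to 208359961, 86.6% ± 6.80, SD, n = 2). Distal ones lay 61900 bp from the assigned end of FGF12 (89.3%), 62806 bp from AGA (89.8%) and within TARS3 (84.5%) and ACOT7 (87.1%). Another 1496 peaks were between 40% and 60% in both replicates. The strongest of these lay within ABCA7 on chromosome 19 (1062262 to 1063503, 43.4% ± 0.422, SD, n = 2, with 435 and 1207 reads), and others within RYR1 (46.8%), ATRIP (44.6%) and DOCK6 (51.4%).

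The 2 strongest distal peaks without methylation lay on sequence resembling mitochondrial DNA. The peak on chromosome 1 at 629037 to 634960, with 155643 and 118923 CpG reads, was at 1.16% ± 0.918 and overlaps 7 annotated nuclear copies of mitochondrial genes, MTND1P23 and MTCO1P12 among them. That on chromosome 5 at 134925098 to 134928532 was at 1.28% ± 1.10 (SD, n = 2) and overlaps 4. In all, 26 autosomal peaks overlap such copies and hold 1.40% and 0.823% of the CpG reads in peaks. Mitochondrial reads that align to such copies would be counted in these peaks.

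The replicates gave similar methylation per peak, with replicate 2 slightly higher at unmethylated regions. Across the 40703 tested peaks, which are not independent replicates, Pearson's r between replicates was 0.907 and Spearman's rho 0.846, and 90.6% of peaks fell in the same class. Fisher's exact test per peak (two-sided, Benjamini-Hochberg adjusted) called 3210 peaks, 2925 higher in replicate 2 and 285 higher in replicate 1, with a median absolute difference of 1.37 points. After the median of CpG-dense peaks was taken off each library, an alternative chosen after the data were examined, it called 685, 337 higher in replicate 2 and 348 higher in replicate 1. That median came from 5678 of the same peaks, so the balance of these calls is partly set by the correction. Of the 3210, 2746 were under 20% in both. The largest differences were in shallow peaks, such as that within CEP85L on chromosome 6 (118685932 to 118686116), at 26.9% of 26 reads and 100% of 14 (adjusted p = 0.00052 by Fisher's exact test). The test compares these libraries, not conditions, and treats reads as independent. Scaled by an overdispersion of 2.90, a chi-square test called 23 peaks. That factor was computed over all tested peaks with the difference between libraries left in, so it does not measure shared reads alone.

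Mitochondrial CpGs are expected to be largely unmethylated, so their level is an upper limit of failed conversion in that DNA. They read 0.722% (95% Wilson interval 0.719% to 0.726%) in replicate 1 and 2.41% (2.40% to 2.42%) in replicate 2, from 21952388 and 19971881 reads. The intervals do not overlap. In 5678 CpG-dense, deeply read autosomal peaks the medians were 0.385% and 1.31%.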

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

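Gene ends on chromosome X, where no peak was listed and which entered no comparison, carried a median methylation of 2.73% over 482 genes (1.23% and 3.81% in the replicates), above all of 10000 autosomal lists matched on CpG density and coverage (median 1.76%, highest 2.21%; permutation p = 0.0002, the smallest these lists can give); between 5% and 50% lay 25.5% of these ends, against 9.36% on the autosomes. The comparison was chosen after the values were seen.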

How the results depend on the processing

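Differences between regions kept their direction under the alternatives run, but the excess of calls higher in replicate 2 (2925 against 285) was lost with the unmethylated floor taken off (337 against 348). The floor came from some of the same peaks, so that balance is partly set by the correction. Among the 35025 peaks not used for the floor, 46.6% of the calls left were higher in replicate 2. Leaving out 1 of 2 replicates always moves a mean by less than the SD, so those 24 values say nothing on stability. Of the other 62, 19 stayed within the replicate spread or, for counts, within 1.5 times. The alternatives with the unmethylated floor taken off, shared gene ends counted once, nuclear mitochondrial copies left out or the CpG-richer end of every gene were chosen after the data were examined; the cause of the changes was not tested. The per-peak count was 23 with the scaled chi-square and 685 with the floor taken off. Inside minus outside was −28.4, −11.6 and −70.7 points for CpGs with at least 5 reads, at least 10 reads, and outside at 2000 to 10000 bp. Classes under 20%, intermediate and over 80% were 82.8%, 16.7% and 0.411% (30 reads), 72.2%, 26.4% and 1.46% (5 reads), 84.8%, 14.9% and 0.308% (stricter peaks), 62.9%, 36.9% and 0.233% (limits 10 and 90), 82.0%, 15.5% and 2.46% (limits 30 and 70), and 71.0%, 27.7% and 1.29% (CpGs weighted equally). Gene end minus distal, as median and as percent over 80%, was −5.53 and −0.579 (30 reads), −10.1 and −1.92 (5 reads), −4.81 and −0.483 (stricter peaks), −8.04 and −1.30 (500 bp), −10.2 and −1.43 (wider window), and −10.2 and −1.33 (every annotated gene). Spearman's coefficient was −0.574 with density, −0.338 with signal and −0.244 with signal within deciles at 30 reads, and −0.234 within deciles for stricter peaks. Lists past the test, 5 as reported, were 3 with 250 bp, 3 with 50 reads, 3 with shared ends counted once, 4 without replicate 1, 2 without replicate 2, 4 with coverage matched, 5 with the CpG-richer end of every gene, 6 with 1000 bp and 6 with 10 reads. The germline and meiosis list passed in all 9 alternatives run (adjusted p 0.0007 to 0.0026 by permutation), though its median was 38.7% with 50 reads; imprinted genes passed in 8 (up to 0.051), HOX genes in 8 (up to 0.90), neural progenitor genes in 5 (up to 0.25) and protocadherins in 2. Leaving out a replicate gave −66.5 to −58.2 points for inside minus outside, −9.22 to −8.93 for gene end minus distal and 0.722% to 2.41% for mitochondrial CpGs. Motif comparisons were not run, and the per-peak test has no value with a replicate left out. Depth limits low-coverage gene ends, many with under 50 reads.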

Other observations

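All tests in this part were chosen after the data were examined; those of background share, flank coverage and CpGs outside peaks had their outcomes stated before the values were seen, while those of conversion, closed chromatin and a lost imprinted copy were set or revised after values were seen. Among 12570 measured autosomal gene ends, methylation and closure went together: 270 were over 80% in both replicates and 9 of those (3.33%) had a peak within 1000 bp, against 87.8% of the 11738 ends under 20% in both. The 9 included ADAD2 and PRSS50, known from testis, with peaks 71 bp and 154 bp from the end and methylation of 85.1% and 81.2%. They were named after their values were seen.

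Unmethylated gene ends without a peak, 1433 or 11.4% of those measured, were over-represented in a few gene families, which hold 101 of them. Of 225 families defined by the letters of their symbols, 7 passed Fisher's exact test (one-sided, adjusted): HOX genes with 21 of 28 (adjusted p = 1.65e-12), WNT signalling genes with 9 of 12 (adjusted p = 5.7e-05), metallothioneins with 7 of 9 (0.000408), collagens with 13 of 31 (0.000666), PRDM zinc finger proteins with 7 of 13 (0.00851), KCNK potassium channels with 6 of 12 (0.0351) and genes with placeholder LOC symbols with 38 of 160 (0.000408). Members included WNT1, WNT3A, WNT7A, MT1X, MT3, PRDM13 and PRDM16. HOX and metallothionein genes are clustered, so the p-values are too small. For ends over 80%, none of the 225 families passed (8 had an unadjusted p under 0.05).

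Replicate 2 read higher at unmethylated peaks and in mitochondrial DNA. More fragments of closed, methylated nuclear chromatin would weigh most where a peak has few reads per CpG. In CpG-dense peaks the gap was 0.904 points in the lowest of 4 groups by reads per CpG (median 24.4) and 0.896 in the highest (58.1). Their ratio of 1.01 (95% bootstrap interval 0.966 to 1.05) lies below the 2.38 that such fragments need, which argues against them as the whole cause. Incomplete conversion was tested by taking the median of the dense peaks off each library. Among the 35025 peaks not used for that median, calls went from 1413, 80.3% higher in replicate 2, to 534, 46.6% higher (95% interval 42.4% to 50.9%), so a shift of the same size in all peaks may account for the one-sided calls. Lower conversion in replicate 2 would give such a shift, but the test does not tell it from other uniform shifts. Whether dense peaks and mitochondrial DNA convert at the same rate was not tested, and neither was a biological explanation.

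Whether background explains the 29 distal peaks over 80% was tested only in part. Reads expected from CpG coverage 2000 to 10000 bp away made up a median of 8.28% and 15.9% of their reads in the replicates, a mean of 12.1%, against 4.75% and 9.91% in other distal peaks. The share passed 50% in 0 and 1 of the 29, so background at that level did not make up most reads of nearly all of them. Called peaks hardly ever pass 50%: only 0.0755% and 0.337% of those other peaks did. The test therefore cannot tell on background higher at the peaks than around them, which remains open. Flank coverage was 1.23 times that of other distal peaks, which argues against wide stretches of excess reads. Narrow repeats whose reads share an alignment were not tested and remain open, and no biological explanation was tested.

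The assigned ends of imprinted genes known for a methylated copy read far below 50%. These ends need not be the control regions, and where they are not, the 2 tests below cannot tell. Loss of that copy at all of them should leave gene ends at the level of matched lists. Their median of 5.03% (17 genes, all in the imprinted list, so an excess was known) was at percentile 99.99, with 98.3 in replicate 1 (2.09%) and 100 in replicate 2 (7.82%). Against lists matched on coverage as well it was at percentile 84.8 in replicate 1 and 99.88 in replicate 2, and CpGs outside peaks were within the matched range, so loss remains open. If open fragments came mainly from the unmethylated copy, CpGs outside peaks within 2000 bp should exceed matched genes. CpGs inside peaks were at 3.24% in the 10 genes with enough reads there, a smaller set. The median outside peaks was 20.3% in 16 genes against 17.6% in matched lists, at percentile 68.3. By replicate it was 11.3% against 14.0% and 22.3% against 20.5%, below and above the matched median (percentiles 26.8 and 61.7). The replicates disagree, so this explanation stays open, and no biological explanation was tested.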
